A study of Mus musculus with 54 samples.

How the data were processed

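Mice carried a green fluorescent reporter in the Fgd5 locus, per the labels' protocols, and HSC were sorted by surface markers and by that reporter. Total RNA was copied to cDNA with SMART-Seq v4 and made into libraries with Nextera XT, per the labels' protocols. This kit copies RNA from its poly(A) tail with full-length cDNA, marks no strand and adds no molecular tags (UMIs), so copies of 1 molecule made by PCR cannot be removed and a count is a count of reads, not of molecules. Reads were aligned with STAR 2.5.2b to mm10 and counted per gene with featureCounts of Subread 1.5.1, per the submitters' processing notes. The deposited values are integer read counts per gene and library with no scaling, per the file headers, which name 1 alignment per column and also give each gene's exons and summed exon length in bases. The gene annotation, the treatment of reads that fit several places and the strand setting are not given in the sources used here.

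The table holds 24421 genes and 54 library columns. Column names give only part of a group: those of 24 h name no radiation, and those given to 1 h name no time. A column was given to a group where its name and the number of samples that the labels give for each group left a single group, which holds for 39 columns and for 1 h rests on the columns that name 24 h filling the irradiated groups of that time. The 15 columns of non-irradiated vehicle mice name no time, could be of either, and were not used, nor was the length column. Comparisons that need those mice are not reported here: radiation with vehicle at 1 h and 24 h and its difference between times, dmPGE2 without radiation, dmPGE2 by radiation, irradiated dmPGE2 mice against non-irradiated vehicle mice, the vehicle controls over time, radiation by sex, and dmPGE2 along the radiation effect. Libraries are numbered here from 1 within each group in the order of the table, and these numbers carry no pairing. At 24 h libraries 1 to 4 are female and 5 to 8 male, as the column names state. Counts of Xist against the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y went against the stated sex in 0 of 16 libraries, and at 1 h, where columns name no sex, they gave the labels' number of females and males in each group.

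The tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise. After the columns were read, 3 things changed. Sex could not be a term of the model, since 1 h columns do not give it. Radiation under dmPGE2 at 1 h, and time with radiation and vehicle, were added as comparisons. The sexes were compared within the 16 libraries of 24 h alone.

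Differences were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (count minimum 10), which left 14061 (14054 for the sexes), libraries were scaled by TMM, and a robust quasi-likelihood model with 1 mean per group was fitted to 39 libraries (common dispersion 0.128, 34 residual degrees of freedom). Adjusted p values are Benjamini-Hochberg values from that test, and a gene is called at an adjusted p below 0.05. Log2 fold changes carry a standard error (SE) derived from the test, as the absolute log2 fold change divided by the square root of its F statistic. CPM are counts scaled to library size with TMM factors, and log2 CPM use a prior count of 3. Summed CPM of marker lists are the exception, scaled to the total count alone without TMM factors and taken before genes were filtered. DESeq2 1.42.0 served as an alternative. Gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with p adjusted over the lists of a comparison; the alternative estimates that correlation from the data. The median, mean and test of a list differ in sign only in lists that were not called. Counts "adjusted over the list alone" are calls with Benjamini-Hochberg adjustment within the list. The lists cover p53 targets, double-strand break repair, anti- and pro-apoptotic genes, G1/S and G2/M, quiescence, immediate early genes, cAMP and CREB targets, PGE2 receptors and prostanoid metabolism, Wnt targets, HSC identity, homing, NF-kB, type I interferon, NRF2, hypoxia and glycolysis, oxidative phosphorylation, integrated stress and unfolded protein response, heat shock, ribosomal proteins, lymphoid-primed progenitors, and markers of 10 other cell types. Some genes belong to several lists, so the lists are not independent results. Bbc3, Bax, Pmaip1 and Apaf1 are both p53 targets and pro-apoptotic genes, and Sesn2 is in the p53 and integrated stress lists. Nr4a1, Fosb, Fosl2, Atf3 and Dusp1 are in both the immediate early and the cAMP and CREB lists. Btg2 is in the p53, quiescence and immediate early lists, and Cdkn1a in the p53 and quiescence lists. Other genes are shared as well.

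Named genes are those with the 10 highest and 10 lowest log2 fold changes (5 and 5 in comparisons beyond the main ones) among called genes with a mean log2 CPM of at least 2, counted in most libraries of the higher group and, at 24 h, with the same sign in both sexes, together with list members of smallest p and marker genes fixed beforehand. Some genes that meet this rule are not reported here. Because strand was not kept, overlapping genes share reads. Of 71 named genes checked against GENCODE vM21, 13 share exon bases with another gene, and the values of 5 are the most uncertain: Gpr65 (511 of 2069 bases), Phlda1 (727 of 2205), Tuba8 (368 of 2263), Txnip (606 of 3123) and Xist (1980 of 17946). Fam212b is not in that annotation under this symbol. Among the genes 27 carry a spreadsheet date instead of a symbol and none was used by name, and 0 genes are named as mitochondrial, so the mitochondrial share could not be checked.

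In simulated counts on the real library sizes, with 50 genes changed 1.5-, 2-, 3- and 4-fold each, the test recovered 42, 66, 74 and 82% for dmPGE2 at 1 h, 52, 82, 78 and 82% at 24 h, 26, 52, 76 and 76% for the difference between times, 60, 62, 78 and 78% for radiation under dmPGE2, 46, 74, 84 and 86% for time, 36, 60, 76 and 80% for sex and 4, 22, 48 and 68% for dmPGE2 by sex. Of the genes called, 5.04, 3.92, 5.74, 2.11, 5.23, 4.55 and 6.58% were false in these 7 comparisons. In each, 0 of 32 unchanged lists was called. The simulation gave each gene the same dispersion in all groups and held no library far from its group. The real dmPGE2 group at 24 h had such libraries, so these rates may not hold for the comparisons that use it. Every gene was simulated independently of the others. The count of lists therefore cannot show how often camera calls unchanged lists whose genes are correlated.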

Results

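The series asks how dmPGE2, a long-acting analogue of prostaglandin E2, changes gene expression in mouse hematopoietic stem cells (HSC) when it is given before a lethal dose of radiation. Fgd5 reporter mice, whose HSC fluoresce green, received dmPGE2 or ethanol vehicle under the skin 30 min before 8.53 Gy, the dose that kills 50% of the animals. HSC were sorted from bone marrow by their surface markers and the reporter 1 h or 24 h later, and each RNA-seq library came from 1 mouse. The labels give the dmPGE2 dose as 35 µg, but the 3.5 µL of a 0.1 mg/ml solution that they also state would hold 0.35 µg, so the dose is uncertain. The comparisons use 39 of the 54 libraries: 7 not irradiated with dmPGE2 at 1 h, 8 irradiated with vehicle and 8 with dmPGE2 at 1 h, and 8 irradiated with vehicle and 8 with dmPGE2 at 24 h. Total counts per library ran from 19963860 to 22976367, 20437332 to 26217041, 21085900 to 25384366, 19787106 to 24296393 and 17371333 to 22155084 in these groups. The 15 libraries of the non-irradiated vehicle mice are not used here, because the names of their columns do not tell 1 h from 24 h. The effect of radiation without dmPGE2, and of dmPGE2 without radiation, is therefore not reported.

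The first question is what dmPGE2 changed in irradiated HSC at 1 h. Genes that p53 switches on after DNA damage were far lower in the mice that had received dmPGE2. Gdf15, a stress cytokine and p53 target, had 33.6 ± 27.4 CPM (SD, n = 8) against 1205 ± 217 (n = 8) with vehicle, a log2 fold change of -5.17 (SE 0.42, adjusted p = 7.71e-12). Bbc3, which encodes the pro-apoptotic protein Puma, had 23.1 ± 10.4 CPM against 294 ± 48.1 (log2 fold change -3.67, SE 0.20, adjusted p = 1.99e-17). In the opposite direction, Nr4a1, a nuclear receptor gene induced by cAMP, had 701 ± 213 CPM against 47.4 ± 56.7 (log2 fold change 3.89, SE 0.41, adjusted p = 4.44e-09). With edgeR, 934 genes were higher and 995 lower at an adjusted p below 0.05 among 14061 genes tested, and 360 of them differed at least 2-fold.

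Of the 34 p53 target genes measured, 24 fell, 1 rose and 9 were not called (26 lower and 2 higher adjusted over the list alone). The list passed camera (median log2 fold change -1.07, adjusted p = 3.9e-38), and it was the only one of the 7 lists called at 1 h that also passed with an estimated correlation (adjusted p = 0.00036). Among its members, Sesn2, which restrains mTOR signalling, fell by 3.79 on the log2 scale (SE 0.16, adjusted p = 9.24e-21) from 544 ± 73.0 to 39.3 ± 13.5 CPM. Phlda3, an inhibitor of Akt, fell by 4.30 (SE 0.22), Trp53inp1 by 3.72 (SE 0.19) and the cyclin gene Ccng1 by 2.41 (SE 0.13). Mdm2, the ubiquitin ligase that limits p53, fell by 1.77 (SE 0.12), and the cell cycle inhibitor gene Cdkn1a fell by 1.09 (SE 0.13). Bax fell by 0.43 (SE 0.07). The mean of the list per library was 3.99 ± 0.12 log2 CPM (SD, n = 7) in the mice that received dmPGE2 without radiation, 6.21 ± 0.13 (n = 8) with radiation and vehicle, and 4.62 ± 0.24 (n = 8) with radiation and dmPGE2. None of the 8 irradiated dmPGE2 libraries lay within the range of either other group, which ended at 4.13 below and began at 5.96 above.

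**Figure D1:**
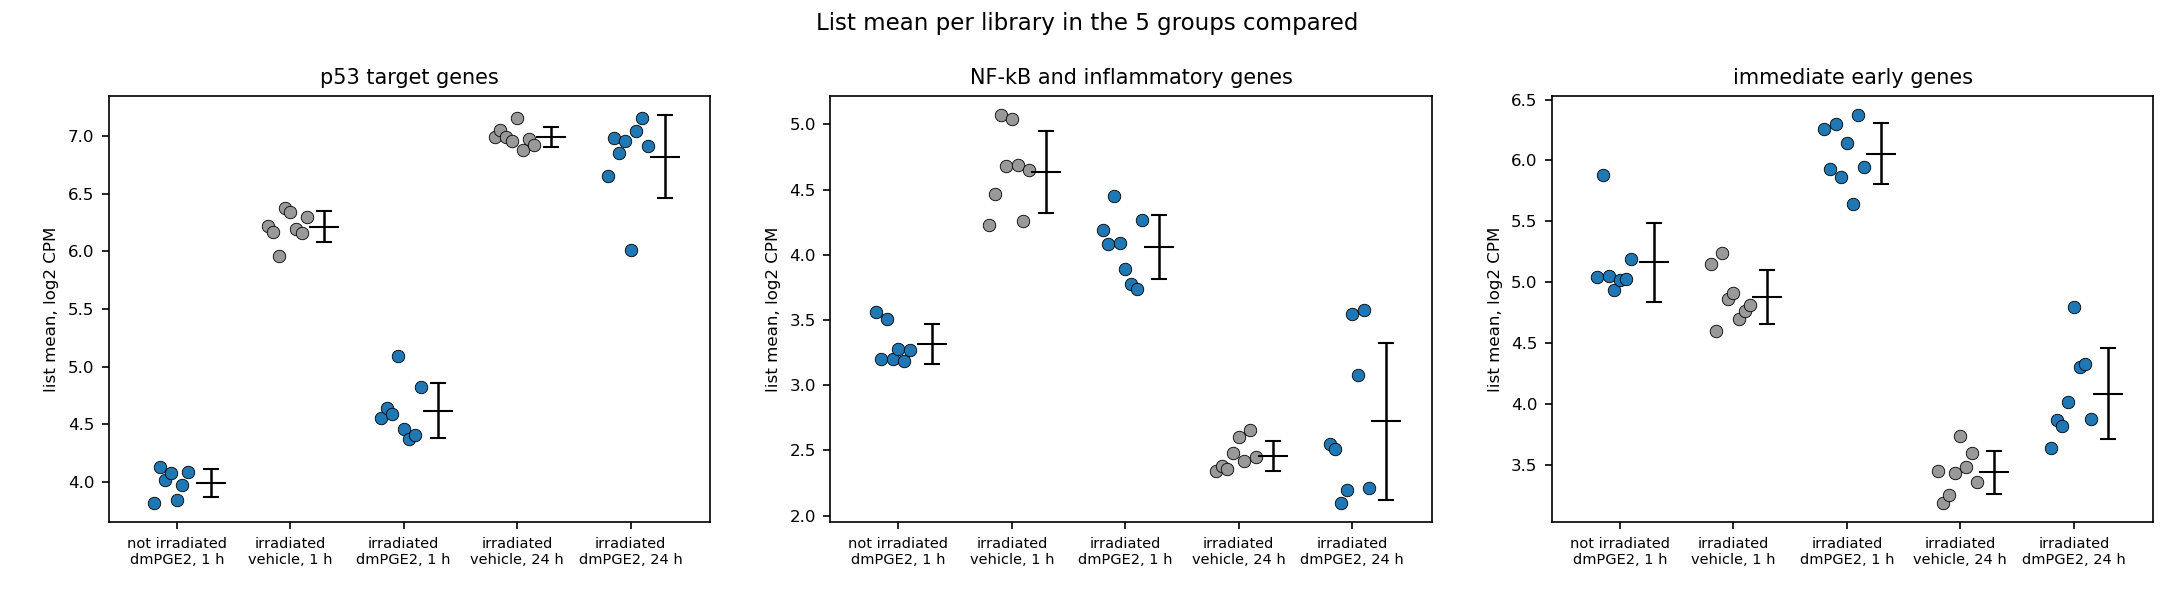
Mean log2 CPM (vertical axis) of the p53 target, NF-kB and immediate early gene lists in each library of the 5 groups (horizontal axis); points are libraries, grey for vehicle and blue for dmPGE2, and bars show the group mean ± SD. The p53 target mean lies at 6.21 with radiation and vehicle and at 4.62 with radiation and dmPGE2 at 1 h, and at 6.99 and 6.82 at 24 h.

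Among called genes with a mean log2 CPM of at least 2, the strongest rise at 1 h was in Ramp3, which encodes a partner of the adrenomedullin receptor (log2 fold change 5.33, SE 0.89, adjusted p = 3.72e-05) and in the tissue factor gene F3 (5.02, SE 0.72). Ramp3 went from 1.66 ± 3.43 to 66.3 ± 29.7 CPM (SD, n = 8 each). Socs3, a feedback inhibitor of cytokine signalling, rose by 4.85 (SE 0.56) and the transcription factor gene Klf2 by 4.84 (SE 0.70). Fos rose by 4.39 (SE 0.58), the urokinase receptor gene Plaur by 3.86 (SE 0.34), Rasd1 by 3.56 (SE 0.53), and Egr1 by 3.19 (SE 0.32). A similar rise was seen for Gpr65, a receptor that senses acid, by 3.10 (SE 0.31). Other strong falls among such genes were in Eda2r (-4.83, SE 0.32), Fam212b (-4.15, SE 0.38), Ddit4l (-4.12, SE 0.32), the thiamine transporter gene Slc19a2 (-3.04, SE 0.19) and Ddias (-2.91, SE 0.18). In mm10, Gdf15 spans bases 70629394 to 70631635 of chromosome 8, Bbc3 16309583 to 16318334 of chromosome 7, Sesn2 132492807 to 132510456 of chromosome 4 and Nr4a1 101266846 to 101274794 of chromosome 15.

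Immediate early genes, which respond to signals without new protein synthesis, rose as a list at 1 h: 11 of 28 were higher, 3 lower and 14 not called (13 higher and 3 lower adjusted over the list alone, median log2 fold change 0.89, camera adjusted p = 5e-07, and adjusted p = 0.1 with an estimated correlation). Dusp2 rose by 1.26 (SE 0.14), while Ier5, a member that p53 also regulates, fell by 2.20 (SE 0.16). The cAMP and CREB targets lie downstream of the PGE2 receptors EP2 and EP4. Of 19 such genes 9 rose, 1 fell and 9 were not called (11 higher and 1 lower adjusted over the list alone, median 1.00, camera adjusted p = 1.4e-06, and adjusted p = 0.17 with an estimated correlation). The cAMP phosphodiesterase gene Pde4d rose by 1.94 (SE 0.21) and Rgs2 by 2.61 (SE 0.30), and Cited2 fell by 2.71 (SE 0.14). The NF-kB and inflammatory list moved the other way, with 12 of 24 genes lower, 1 higher and 11 not called (12 lower and 4 higher adjusted over the list alone, median -1.07, camera adjusted p = 5e-07, and adjusted p = 0.1 with an estimated correlation). The adhesion molecule gene Icam1 fell by 2.86 (SE 0.12), Nfkbie by 2.48 (SE 0.16) and Relb by 2.35 (SE 0.25).

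Smaller shifts were called in 3 more lists. Hypoxia and glycolysis genes had 6 of 25 higher, 0 lower and 19 not called (6 higher adjusted over the list alone, camera adjusted p = 0.0011, and adjusted p = 0.063 with an estimated correlation). Among them were the hexokinase gene Hk2 at 2.07 (SE 0.22) and the growth factor gene Vegfa at 1.83 (SE 0.22). Oxidative phosphorylation genes had 9 of 47 higher and 38 not called (10 higher adjusted over the list alone, median 0.18, camera adjusted p = 6.1e-07, and adjusted p = 0.86 with an estimated correlation). Type I interferon genes had 4 of 26 lower and 22 not called (5 lower adjusted over the list alone, median -0.13, camera adjusted p = 0.019, and adjusted p = 0.9 with an estimated correlation). Irf9 fell by 0.71 (SE 0.11).

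Other lists were not called at 1 h, although single members passed. In the pro-apoptotic list 4 of 17 fell and 1 rose (camera adjusted p = 0.23), and the 4 were Bbc3, Pmaip1 (-2.85, SE 0.34), Bax and Apaf1 (-0.71, SE 0.15). In the quiescence list 5 of 17 fell and 2 rose (camera adjusted p = 0.35), with the antiproliferative gene Tob1 at -2.31 (SE 0.16). In the HSC identity list 8 of 36 rose and 1 fell (camera adjusted p = 0.18), with Hoxa9 at 1.02 (SE 0.15), Gata2 at 0.81 (SE 0.12) and Lmo2 at 0.58 (SE 0.08). Of 43 G1/S genes 3 rose and 1 fell (camera adjusted p = 0.19), and of 55 G2/M genes 2 rose and 2 fell (camera adjusted p = 0.1), the strongest being Gtse1, which binds p53, at -2.86 (SE 0.21). With the tags in the column names as a replicate block, camera did call the G2/M list, as higher (adjusted p = 0.0063). In the NRF2 and oxidative stress list 5 of 22 rose and 1 fell (camera adjusted p = 0.45), and the faller was Nfe2l2, the gene of NRF2 itself, at -1.30 (SE 0.10). The integrated stress list had 3 higher and 4 lower of 23, with a median of 0.07 and a test that points down (camera adjusted p = 0.8). Of 17 PGE2 receptor and prostanoid genes 1 fell (camera adjusted p = 0.53), the receptor gene Ptger4 at -0.87 (SE 0.15). The homing list had 2 higher and 2 lower of 16 (camera adjusted p = 0.74), with the chemokine receptor gene Cxcr4 at -0.78 (SE 0.22). Anti-apoptotic genes had 2 of 13 lower (camera adjusted p = 0.53), double-strand break repair 1 of 33 lower (0.98), heat shock 1 of 14 lower (0.6) and lymphoid-primed progenitor genes 1 of 9 lower (0.8). Ribosomal protein genes had 0 of 76 called (0.26) and Wnt targets 0 of 10 (0.93).

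Few markers of other blood and marrow cells passed at 1 h. Of the megakaryocyte markers 2 of 10 rose (camera adjusted p = 0.12), Rab27b by 1.48 (SE 0.19) and Gp5 by 0.92 (SE 0.26), and of the dendritic markers 1 of 8 rose (camera adjusted p = 0.98), Irf8 by 0.69 (SE 0.22). No gene was called by edgeR among 9 erythroid, 13 neutrophil, 13 monocyte, 6 B cell, 10 T and NK cell, 7 mast cell, 10 endothelial and 8 stromal markers, and camera gave these 8 lists an adjusted p from 0.4 to 0.98. The neutrophil markers summed to a median of 540 CPM with dmPGE2 and 567 CPM with vehicle. Against a fold change of 1.5, 259 genes passed, and 1112 passed at an adjusted p below 0.01.

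A second question is how far irradiated HSC differed from non-irradiated HSC when both had received dmPGE2, at 1 h. Cxcl2, a chemokine that attracts neutrophils, had 81.3 ± 22.7 CPM (SD, n = 8) with radiation and 3.82 ± 1.99 (n = 7) without, a log2 fold change of 4.41 (SE 0.63, adjusted p = 6.73e-05). Gdf15 rose by 4.27 (SE 0.46, adjusted p = 8.95e-08), from 1.74 ± 0.81 CPM without radiation. The early activation marker gene Cd69 rose by 3.41 (SE 0.28), Gadd45b by 2.84 (SE 0.30), Phlda3 by 2.57 (SE 0.23) and Pmaip1, which encodes the pro-apoptotic protein Noxa, by 2.53 (SE 0.38). Zfp36, which destabilises inflammatory mRNAs, rose by 2.24 (SE 0.38), Btg2 by 2.12 (SE 0.18), Phlda1 by 2.08 (SE 0.35) and Bhlhe40 by 2.04 (SE 0.32). Only 4 genes were lower, against 54 higher, and among the 4 were Dusp6, which encodes an ERK phosphatase, at -0.61 (SE 0.15) and Cd93 at -0.40 (SE 0.09). Neither of these was called with the 1 h libraries alone (adjusted p = 0.09 and 0.067). Against a fold change of 1.5, 21 genes passed.

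Immediate early genes and p53 targets rose together after radiation under dmPGE2. Of the 28 immediate early genes 11 rose and 17 were not called (13 higher adjusted over the list alone, median 1.07, camera adjusted p = 1.2e-41), among them Ier5 at 1.93 (SE 0.16) and Junb at 1.69 (SE 0.23). Of the 34 p53 targets 10 rose and 24 were not called (14 higher adjusted over the list alone, median 0.27, camera adjusted p = 4.8e-29), with Cdkn1a at 1.23 (SE 0.13) and Bbc3 at 1.22 (SE 0.20). The NF-kB list had 3 of 24 higher (6 adjusted over the list alone, camera adjusted p = 1.6e-13), including the inhibitor genes Nfkbia at 2.03 (SE 0.19) and Tnfaip3 at 1.66 (SE 0.21). The integrated stress list had 1 of 23 higher (3 adjusted over the list alone, camera adjusted p = 1.5e-06), which was Sesn2 at 0.67 (SE 0.16). These 4 lists also passed with an estimated correlation, with adjusted p of 4.3e-06, 0.00092, 0.0041 and 0.00024. Type I interferon genes had 0 of 26 called and a median of -0.31 (camera adjusted p = 1.4e-08, and adjusted p = 0.24 with an estimated correlation). Another 8 lists passed camera, with adjusted p from 4.9e-05 to 0.045, and each was lost with an estimated correlation, where their adjusted p ran from 0.12 to 0.8. Of the 54 genes that rose with radiation under dmPGE2, 27 were lower and 13 higher with dmPGE2 than with vehicle in irradiated HSC. Both comparisons share the irradiated dmPGE2 libraries. With these divided between the comparisons, 12 to 33 of 25 to 56 genes were lower, against 3.56 to 5.9% of all genes. In the same divisions 5 to 11 genes were higher, and the share of all genes that were higher was not counted.

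At 24 h, HSC of irradiated mice that had received dmPGE2 had lower levels of cell cycle genes than those given vehicle. Of 55 G2/M genes 46 fell, 0 rose and 9 were not called (48 lower adjusted over the list alone, median log2 fold change -0.71, camera adjusted p = 2.3e-23, and adjusted p = 0.19 with an estimated correlation). Among them were the mitotic kinase gene Cdk1 at -0.99 (SE 0.17, adjusted p = 0.00011) and the survivin gene Birc5 at -0.91 (SE 0.22). Of 43 G1/S genes 36 fell, 0 rose and 7 were not called (41 lower adjusted over the list alone, median -0.64, camera adjusted p = 7e-24, and adjusted p = 0.19 with an estimated correlation). The ribonucleotide reductase gene Rrm1 fell by 0.81 (SE 0.14) and the replication factor gene Cdc45 by 0.88 (SE 0.16). Perp, a p53 target with roles in cell adhesion and death, had 62.0 ± 22.5 CPM (SD, n = 8) with dmPGE2 and 183 ± 56.2 (n = 8) with vehicle (log2 fold change -1.56, SE 0.22, adjusted p = 7.15e-06). With edgeR, 1622 genes were higher and 1415 lower, and of these 522 and 144 differed at least 2-fold.

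The 8 dmPGE2 libraries at 24 h were not alike. Libraries 5, 6 and 7, from 3 of the 4 male mice, had scores of -74.6, -64.7 and -80.2 on the second principal component of all 39 libraries (7.5% of the variance), where the lowest of the others was -25. Library 3, from a female mouse, lay alone on the fourth component at -87.8. The G1/S list mean was 6.78 ± 0.09 log2 CPM (SD, n = 8) with vehicle and 6.03 ± 0.54 (n = 8) with dmPGE2, and libraries 5 to 7 held the lowest 3 values. Without these 3 libraries 981 genes passed, 20 of 55 G2/M genes (median of the list -0.59) and 11 of 43 G1/S genes (median -0.34) were still lower, and both lists still passed camera with the preset correlation but not with an estimated one (adjusted p = 0.32 for G1/S and adjusted p = 0.26 for G2/M), in fits chosen after seeing the data. Without library 3 as well, 674 genes passed, with 10 G2/M and 8 G1/S genes lower.

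**Figure D2:**
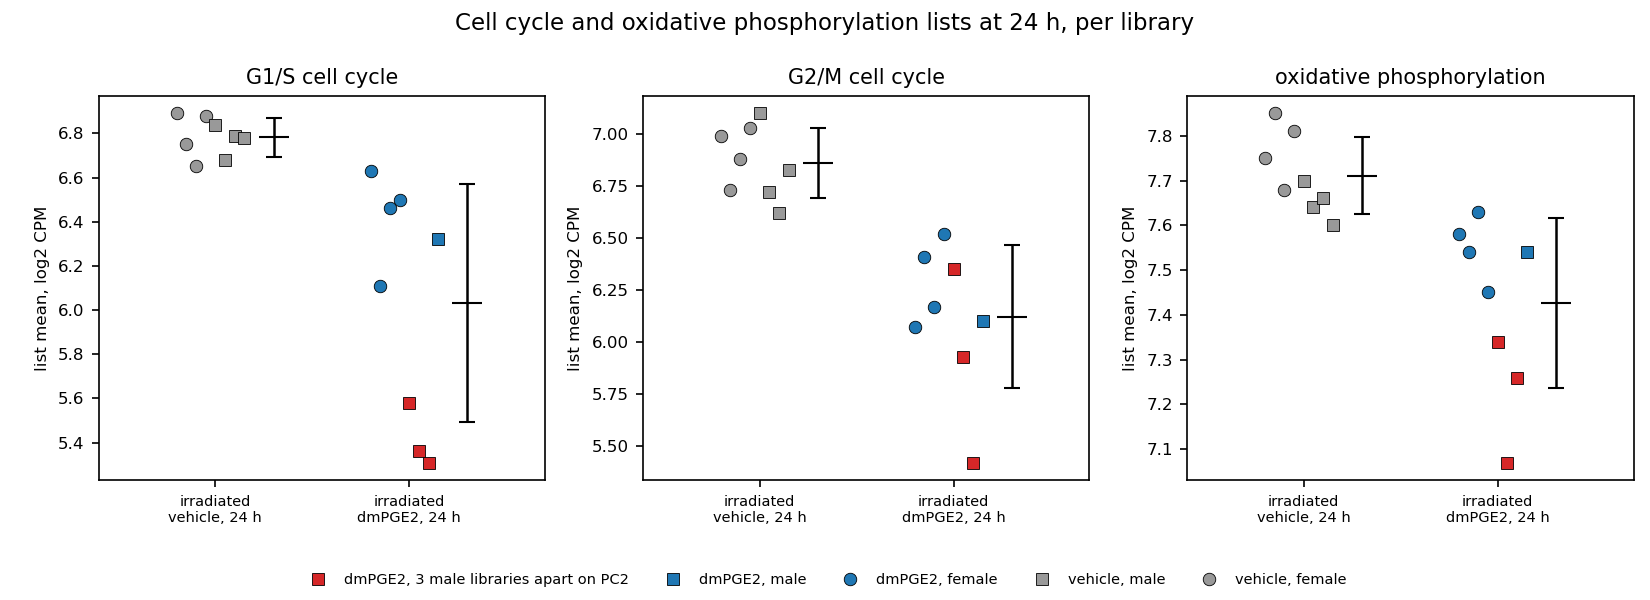
Mean log2 CPM (vertical axis) of the G1/S, G2/M and oxidative phosphorylation lists in each irradiated library at 24 h, vehicle and dmPGE2 (horizontal axis); circles are female and squares male mice, red squares are the 3 male dmPGE2 libraries that lie apart, and bars show the group mean ± SD. All 8 dmPGE2 libraries have a lower G2/M mean (5.42 to 6.52) than all 8 vehicle libraries (6.62 to 7.10).

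Some genes of oxidative phosphorylation, double-strand break repair and the ribosome were also lower with dmPGE2 at 24 h, and no list of these passed with an estimated correlation. Of 47 oxidative phosphorylation genes 28 fell and 19 were not called (37 lower adjusted over the list alone, median -0.25, camera adjusted p = 2.4e-15, and adjusted p = 0.23 with an estimated correlation). The complex I gene Ndufb8 fell by 0.38 (SE 0.08), and 6 of the 47 genes were lower without libraries 5 to 7. Of 33 double-strand break repair genes 9 fell and 24 were not called (10 lower adjusted over the list alone, median -0.33, camera adjusted p = 7.9e-06, and adjusted p = 0.2 with an estimated correlation). The recombination gene Rad54l fell by 1.17 (SE 0.20), and 2 of the 33 were lower without the 3 libraries (median -0.20). Of 76 cytosolic ribosomal protein genes 10 fell and 66 were not called (7 lower adjusted over the list alone, median -0.15, camera adjusted p = 2.1e-07, and adjusted p = 0.59 with an estimated correlation). Without the 3 libraries 0 were called (median -0.08). The p53 targets, lower at 1 h, were not called as a list at 24 h: 4 of 34 were lower and 1 higher (median -0.06, camera adjusted p = 0.059; 1 lower and 0 higher without the 3 libraries), Mdm2 was at -0.05 (SE 0.12, adjusted p = 0.79) and Cdkn1a at -0.21 (SE 0.13, adjusted p = 0.24).

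Some immediate early genes, cAMP targets and HSC identity genes were higher with dmPGE2 at 24 h, and no list of these passed with an estimated correlation. Of 28 immediate early genes 8 rose and 20 were not called (8 adjusted over the list alone, median 0.33, camera adjusted p = 0.003, and adjusted p = 0.3 with an estimated correlation). Among them were Socs3 at 3.89 (SE 0.54), Fosl2 at 2.71 (SE 0.41) and Klf2 at 3.29 (SE 0.68), and 3 were higher without libraries 5 to 7 (median 0.17), where Socs3 was at 2.29, Fosl2 at 1.37 and Klf2, not called, at 0.26. Of 19 cAMP and CREB targets 9 rose and 10 were not called (11 adjusted over the list alone, median 0.87, camera adjusted p = 0.0017, and adjusted p = 0.3 with an estimated correlation). Without the 3 libraries 1 cAMP target was higher and the list was not called (median 0.20, camera adjusted p = 0.19). Of 36 HSC identity genes 11 rose, 2 fell and 23 were not called (11 and 2 adjusted over the list alone, median 0.25, camera adjusted p = 0.014, and adjusted p = 0.54 with an estimated correlation). Gfi1, a repressor that restrains HSC proliferation, rose by 2.24 (SE 0.42; 1.45 without the 3 libraries). Only 1 of the 36 was higher without the 3 libraries, where the list was not called (median 0.08, camera adjusted p = 0.31). The homing list had 5 of 16 higher and 11 not called (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.035, and adjusted p = 0.25 with an estimated correlation). Alcam, an adhesion gene, rose by 1.59 (SE 0.20; 1.06 without the 3 libraries), and the list was not called without the 3 libraries (camera adjusted p = 0.28). The integrated stress list had 10 of 23 higher and 13 not called (10 adjusted over the list alone, camera adjusted p = 0.033, and adjusted p = 0.19 with an estimated correlation). Atf4 rose by 0.50 (SE 0.11), and 5 of the 23 were higher without the 3 libraries. Type I interferon genes had 3 lower and 2 higher of 26 (3 and 2 adjusted over the list alone, median -0.23, camera adjusted p = 0.033, and adjusted p = 0.66 with an estimated correlation). The interferon list was not called without the 3 libraries (camera adjusted p = 0.4).

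Markers of other cells moved at 24 h. Megakaryocyte markers had 6 of 10 lower and 4 not called (8 lower adjusted over the list alone, median -0.71, camera adjusted p = 5.8e-06, and adjusted p = 0.19 with an estimated correlation). Pf4, platelet factor 4, fell by 1.88 (SE 0.36) from 293 ± 161 to 79.4 ± 53.6 CPM. Neutrophil markers had 3 of 13 higher and 10 not called (3 adjusted over the list alone, median 1.21, camera adjusted p = 0.00055, and adjusted p = 0.3 with an estimated correlation). The 3 were the protease gene Prtn3 at 1.60 (SE 0.16), S100a9 at 3.48 (SE 0.86) and S100a8 at 3.27 (SE 0.84). The list's summed level was a median of 492 CPM (288 to 851) with dmPGE2 and 105 CPM (89.5 to 603) with vehicle. Lymphoid-primed progenitor genes had 4 of 9 higher and 5 not called (6 adjusted over the list alone, camera adjusted p = 0.014, and adjusted p = 0.2 with an estimated correlation). The cytokine receptor gene Flt3 rose by 2.89 (SE 0.48) and Cd34, a surface marker that most adult mouse HSC lack, by 0.59 (SE 0.11). Without libraries 5 to 7, 1 of the 9 was higher, Cd34 at 0.46, and Flt3 was not called (0.89, adjusted p = 0.055). Among lists not called, stromal markers had 4 of 8 higher (camera adjusted p = 0.059), endothelial markers 3 of 10 (0.068), mast cell markers 1 of 7 (0.082), and monocyte markers 2 of 13 (0.3). Erythroid markers had 4 higher and 1 lower of 9 (0.3), dendritic markers 2 higher and 3 lower of 8 (0.54), T and NK cell markers 1 lower of 10 (0.98) and B cell markers 0 of 6 called (0.68). Without libraries 5 to 7, megakaryocyte markers had 4 lower, neutrophil markers 3 higher, stromal markers 3 higher, endothelial and monocyte markers 0 called, erythroid markers 1 higher, and dendritic markers 1 higher and 2 lower. The mast cell list was called there (camera adjusted p = 0.032, and adjusted p = 0.59 with an estimated correlation). The summed endothelial markers ran from 206 to 247 CPM in libraries 5 to 7 and from 106 to 140 CPM in the other 13 libraries at 24 h. The summed stromal markers stood at 474 CPM in dmPGE2 library 1, from a female mouse, and at 20.5 to 107 CPM in all other libraries at 24 h.

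Larger fold changes at 24 h were called in genes of few counts, such as the stromal marker gene Lepr, with 229 counts over the 8 dmPGE2 libraries and 0 over the 8 vehicle libraries. Among called genes with a mean log2 CPM of at least 2 and the same sign in both sexes, the strongest rise was in Pdcd1, the gene of the immune checkpoint receptor PD-1 (log2 fold change 5.14, SE 1.01, adjusted p = 0.000481), followed by Clec4d (4.82, SE 0.62) and the mucin gene Muc1 (3.91, SE 0.60). Pdcd1 had 79.4 ± 174 CPM with dmPGE2 and 2.25 ± 1.81 with vehicle (SD, n = 8 each). Next came Socs3, the chemokine gene Ccl9 (3.68, SE 0.58), S100a9, Klf2, S100a8, the interleukin 10 receptor gene Il10ra (3.16, SE 0.61) and Rasd1 (3.08, SE 0.53). Of these, Pdcd1, Klf2, Il10ra and Rasd1 were not called without libraries 5 to 7 (log2 fold changes 0.69, 0.26, 0.74 and 0.88). Strong falls were seen in the chemokine gene Cxcl10 (-2.23, SE 0.66, adjusted p = 0.0135), Pf4, Ifit1bl1 (-1.87, SE 0.39), the thrombin receptor gene F2rl2 (-1.80, SE 0.36) and Perp. They were followed by the tubulin gene Tuba8 (-1.54, SE 0.27), the carboxylesterase gene Ces2e (-1.53, SE 0.49), Ano3 (-1.50, SE 0.52) and Sardh (-1.45, SE 0.33). Ces2e and Ano3 were not called without the 3 libraries (-1.12 and -1.15). In mm10, Pdcd1 spans 94038305 to 94052553 of chromosome 1, Cxcl10 92346639 to 92348889 of chromosome 5, Perp 18845071 to 18857072 of chromosome 10 and Socs3 117966087 to 117969366 of chromosome 11. The count of 3037 genes became 1507 with only the 24 h libraries in the fit, 1800 with sex as a term in that fit, 1540 at an adjusted p below 0.01 and 200 against a fold change of 1.5. Within females (4 against 4) 42 genes passed and within males 2189. Both come from 1 fit of the 16 libraries of 24 h, so the spread between libraries was estimated over both sexes.

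Further lists were not called at 24 h. NF-kB genes had 6 of 24 higher and 1 lower (camera adjusted p = 0.059), hypoxia and glycolysis 6 of 25 higher and 1 lower (0.32), with the glucose transporter gene Slc2a1 at 1.02 (SE 0.16; 0.49 without libraries 5 to 7). Quiescence genes had 4 of 17 higher and 1 lower (0.68), with the cell cycle inhibitor gene Cdkn1c at 0.76 (SE 0.20). Without libraries 5 to 7, 0 of the 17 were called, and Cdkn1c was at 0.44 (adjusted p = 0.17). PGE2 receptor and prostanoid genes had 3 higher and 4 lower of 17 (0.99), with Ptger4 at 0.72 (SE 0.15; 0.43 without these libraries) and Ptger3 at -0.40 (SE 0.08). Anti-apoptotic genes had 3 higher and 2 lower of 13 (0.96), with Bcl2l1 at -0.63 (SE 0.10). Pro-apoptotic genes had 2 higher and 3 lower of 17 (0.38), NRF2 genes 3 higher and 4 lower of 22 (0.54), heat shock genes 2 lower of 14 (0.25) and Wnt targets 1 lower of 10 (0.71). Without libraries 5 to 7 NF-kB genes had 1 higher and 1 lower, prostanoid genes 1 higher and 2 lower, anti-apoptotic genes 0 higher and 2 lower, pro-apoptotic genes 1 higher and 0 lower, and NRF2 genes 1 higher and 1 lower, with 0 heat shock genes and 0 Wnt targets called.

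Another question is whether the dmPGE2 effect differed between 24 h and 1 h, tested as the difference of both differences. Genes that were lower with dmPGE2 at 1 h were among those that differed most. Gdf15 was 5.92 higher on the log2 scale in its response at 24 h (SE 0.53, adjusted p = 2.9e-10), Eda2r 4.59 (SE 0.41), Phlda3 4.34 (SE 0.29) and Fam212b 4.05 (SE 0.48). Of the 34 p53 targets, 22 had a higher and 1 a lower response at 24 h (23 and 3 adjusted over the list alone, median difference 0.89, camera adjusted p = 9e-16, and adjusted p = 0.081 with an estimated correlation). Egr1 (-3.68, SE 0.43), Nr4a1 (-3.38, SE 0.53) and the anticoagulant receptor gene Thbd (-2.97, SE 0.31) had a lower response at 24 h, as had the interleukin 21 receptor gene Il21r (-3.28, SE 0.26). Il21r went from 41.6 ± 6.14 CPM with vehicle to 324 ± 64.7 with dmPGE2 at 1 h and stood at 269 ± 27.1 and 216 ± 72.1 at 24 h (SD, n = 8 each). Il10ra had a higher response at 24 h (4.11, SE 0.84) but was not called without libraries 5 to 7 (1.69). In all, 3313 of 14061 genes differed, 1668 higher and 1645 lower at 24 h.

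The NF-kB list had a higher response at 24 h in 11 of 24 genes and a lower one in 0 (12 higher adjusted over the list alone, median difference 1.29, camera adjusted p = 3.6e-06, and adjusted p = 0.19 with an estimated correlation). Lower responses at 24 h were found for 28 of 43 G1/S genes (32 adjusted over the list alone, median -0.81), 39 of 55 G2/M genes with 1 higher (42 and 1, median -0.91) and 39 of 47 oxidative phosphorylation genes (42, median -0.46). Their camera adjusted p values were 1.2e-15, 1.2e-15 and 2.7e-17, and 0.31 for each with an estimated correlation. Megakaryocyte markers had 6 of 10 lower (7, median -0.91, camera adjusted p = 9.3e-06, and adjusted p = 0.19 with an estimated correlation). Ribosomal protein genes had 11 of 76 lower (4, median -0.21, camera adjusted p = 6.8e-06, and adjusted p = 0.77 with an estimated correlation). Double-strand break repair genes had 8 lower and 1 higher of 33 (8 and 1, median -0.31, camera adjusted p = 0.0033, and adjusted p = 0.4 with an estimated correlation). Neutrophil markers had 3 of 13 higher (3, median 1.43, camera adjusted p = 0.044, and adjusted p = 0.73 with an estimated correlation). Without the 3 male libraries 24 G1/S genes (median -0.53) and 27 G2/M genes (-0.81) had a lower response, 10 NF-kB genes a higher and 1 a lower one (median 0.65), 21 p53 targets a higher one, and the p53 list passed with an estimated correlation too (adjusted p = 0.0027). There, 3 double-strand break repair genes were lower and that list was not called (camera adjusted p = 0.089), and 0 ribosomal protein genes were called. Immediate early genes and cAMP targets, not called with all libraries (camera adjusted p = 0.18 and 0.32), had a lower response without the 3 (camera adjusted p = 0.0042 and 0.0015, and adjusted p = 0.43 and 0.34 with an estimated correlation). Among all genes, 159 rose at both times where independent lists would share 108, 45 fell at both times (100), 142 rose at 1 h and fell at 24 h (94), and 138 fell at 1 h and rose at 24 h (115). The log2 fold changes of the 14061 genes at both times had a Pearson r of 0.092 across genes, which are not independent replicates. Against a fold change of 1.5, 373 genes differed, 1758 at an adjusted p below 0.01, and 2158 without libraries 3, 5, 6 and 7.

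**Figure D3:**
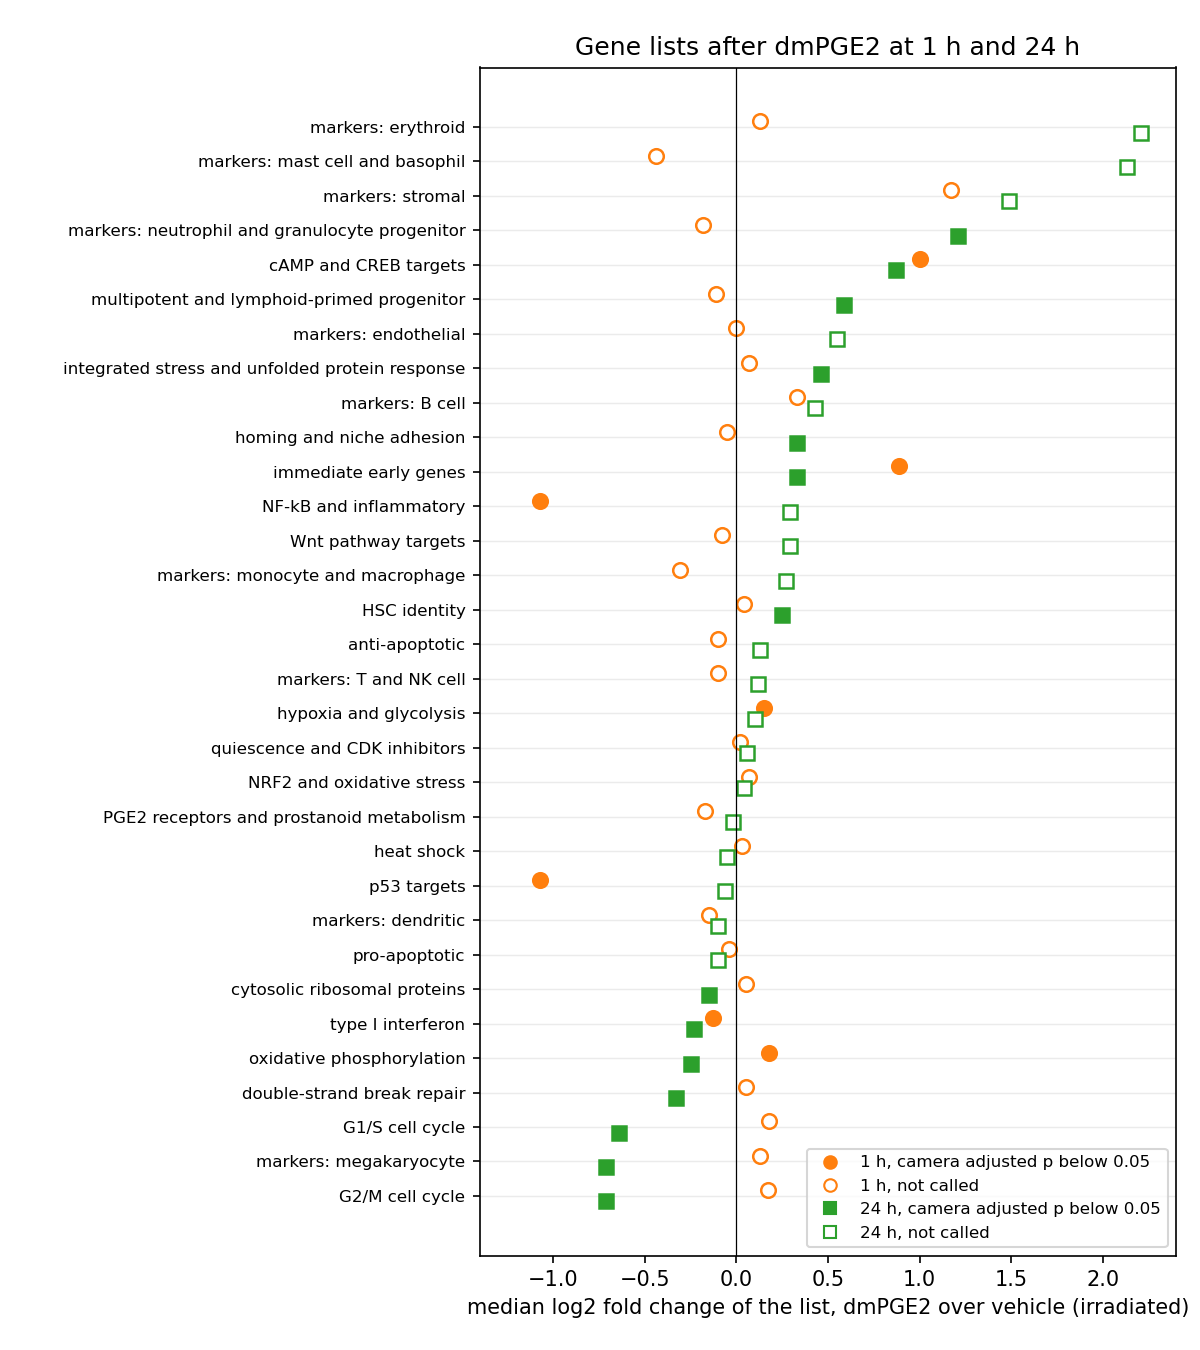
Median log2 fold change of each gene list, dmPGE2 over vehicle in irradiated HSC (horizontal axis), at 1 h (orange circles) and 24 h (green squares), n = 8 libraries per group; filled symbols are lists with a camera adjusted p below 0.05 at the preset correlation. The p53 targets lie at -1.07 at 1 h and -0.06 at 24 h, and the G2/M genes at 0.17 and -0.71.

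Between 1 h and 24 h after radiation with vehicle, Ces2e rose from 0.232 ± 0.335 to 66.5 ± 18.8 CPM (SD, n = 8 each; log2 fold change 8.09, SE 0.70, adjusted p = 5.64e-12) and the protease inhibitor gene Serpine2 by 5.89 (SE 0.26). Sulf2 rose by 4.87 (SE 0.23), Id1, an inhibitor of differentiation, by 4.14 (SE 0.30) and Cox6b2 by 4.03 (SE 0.19). Cd69 fell by 5.54 (SE 0.30), Tnfaip3, an inhibitor of NF-kB, by 5.11 (SE 0.24), Phlda1 by 4.33 (SE 0.37), Cd83 by 4.27 (SE 0.45) and Rnd1 by 4.24 (SE 0.55). Among p53 targets 19 of 34 were higher and 9 lower (19 and 9 adjusted over the list alone, camera adjusted p = 1e-04, and adjusted p = 0.36 with an estimated correlation). Bax was 2.19 higher (SE 0.08), and Bbc3 was lower at -1.32 (SE 0.19). The library numbers in the column names end at 72 at 1 h and begin at 86 at 24 h, so time and library batch cannot be told apart in the 3212 higher and 3732 lower genes.

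Ribosomal protein genes were higher at 24 h in 75 of 76 cases (75 adjusted over the list alone, median 0.77, camera adjusted p = 1.2e-38). So were oxidative phosphorylation genes in 45 of 47 (45, median 0.76, 4.1e-24) and G2/M genes in 49 of 55 with 1 lower (49 and 1, median 1.17, 8.4e-19). Type I interferon genes were higher in 18 of 26 and lower in 1 (18 and 1, median 0.99, 3.5e-08), G1/S genes higher in 18 of 43 and lower in 1 (18 and 1, 0.00032) and megakaryocyte markers higher in 7 of 10 (8, 0.00089). NF-kB genes were lower in 14 of 24 and higher in 1 (15 and 1, median -1.92, 3.9e-10), and immediate early genes lower in 20 of 28 and higher in 1 (20 and 1, median -1.60, 1.6e-07). So were cAMP and CREB targets in 16 of 19 (16, median -1.63, 1e-05) and neutrophil markers in 8 of 13 (8, median -2.07, 0.035). None of these lists passed with an estimated correlation, where the adjusted p ran from 0.076 for NF-kB genes to 0.65 for G1/S genes. In lists that camera did not call, erythroid markers had 6 of 9 lower and 1 higher (median -2.32, camera adjusted p = 0.058), lymphoid-primed genes 5 of 9 lower (median -1.52, 0.098), mast cell markers 4 of 7 lower (median -3.36, 0.17), dendritic markers 5 of 8 lower and 1 higher (0.2) and endothelial markers 5 of 10 lower and 2 higher (0.91). The stem cell factor receptor gene Kit, used in the sort, fell by 1.13 (SE 0.11). Against a fold change of 1.5, 1824 genes passed.

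Sex was given by the column names at 24 h, so female and male mice were compared over the 16 irradiated libraries of that time (8 against 8). Xist, the RNA that silences the X chromosome in females, was 8.45 higher on the log2 scale in females (SE 0.44, adjusted p = 3.31e-10). Myl10 was 2.80 higher (SE 0.31), Cd5l 1.53 (SE 0.28), Adamtsl5 1.00 (SE 0.19) and Fkbp11 0.93 (SE 0.16). Lmcd1 was lower in females (-2.12, SE 0.40), as were the signalling regulator gene Rgs1 (-1.07, SE 0.18), Slco3a1 (-0.65, SE 0.12) and Txnip (-0.62, SE 0.09, adjusted p = 0.00398). With edgeR, 9 genes were higher and 12 lower of 14054 tested. The count was 1505 without library 8, the 1 male dmPGE2 library that does not lie apart, 675 with 39 libraries in the fit and 462 with DESeq2. A fit without libraries 5 to 7 leaves library 8 as the only male dmPGE2 library, so it cannot tell sex from that 1 mouse. In that fit Xist was at 10.28, and whether the other 8 genes named here hold without libraries 5 to 7 cannot be told. Camera called 13 lists. Among them were G1/S genes, higher in females (0 called, 15 higher adjusted over the list alone, median 0.32, adjusted p = 1.4e-14, and adjusted p = 0.29 with an estimated correlation). HSC identity genes were lower in females (0 called, 14 lower adjusted over the list alone, median -0.25, adjusted p = 4.1e-07, and adjusted p = 0.12 with an estimated correlation). Megakaryocyte and monocyte markers were higher in females as lists with 0 genes called (medians 0.37 and 0.33, camera adjusted p = 0.0025 and 0.02). None of the 13 passed with an estimated correlation. Without libraries 5 to 7, in the fit with 1 male dmPGE2 library, the medians were 0.05 for the G1/S list and -0.13 for the HSC identity list. That fit was chosen after seeing the data. The medians there were 0.36 for megakaryocyte, 0.61 for monocyte, -3.47 for mast cell and -0.15 for T and NK cell markers. The mast cell mean was 3.84 log2 CPM in library 8 and from -1.83 to 2.65 in the female dmPGE2 libraries. With vehicle the G1/S means ran from 6.65 to 6.89 log2 CPM in females and from 6.68 to 6.84 in males.

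Whether the dmPGE2 effect at 24 h differed between the sexes was tested as an interaction over the same 16 libraries. No gene passed with edgeR (0 of 14054; 1670 had an unadjusted p below 0.05), while DESeq2 called 34. Genes of small p were Pfas, an enzyme gene of purine synthesis, with a response 1.72 higher in females (SE 0.32), and the asparaginyl-tRNA synthetase gene Nars (0.60, SE 0.13). Dock10 (-1.46, SE 0.30) and the transcription factor gene Zbtb16 (-3.61, SE 0.78) followed, each of the 4 with an adjusted p of 0.28. Camera called 7 lists, led by G1/S genes (1 higher adjusted over the list alone, median 0.64, adjusted p = 3.6e-19, and adjusted p = 0.41 with an estimated correlation). Heat shock genes were another (6 higher adjusted over the list alone, median 0.55, adjusted p = 0.00032, and adjusted p = 0.41 with an estimated correlation). The G1/S mean was 5.31 to 5.58 log2 CPM in male dmPGE2 libraries 5 to 7, while male library 8, at 6.32, lay within the range of the female dmPGE2 libraries (6.11 to 6.63). The heat shock mean was 5.52 to 5.74 in libraries 5 to 7, 6.04 in library 8 and 6.07 to 6.35 in these females. Without library 8, 864 genes passed, and 90 with 39 libraries in the fit.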

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

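The tests of difference between times were planned, and the search for samples that stand apart was run over values already in the tables. In groups of 7 or 8, a library was listed when the gap to its neighbour was too large for the group's range (Dixon's test at 95%). Chance lists about 1 in 20 groups: 2 of 20 library measures, 12 of 160 list means and 20 of 141 named-gene levels were listed.

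At 24 h, irradiated dmPGE2 library 5 (male) had the lowest p53 target mean of its group (6.01 log2 CPM, next 6.65), together with the lowest Gdf15 (4.18, next 6.63), Phlda3 (7.50, next 8.44), Perp (4.37, next 5.56), Fam212b (4.41, next 5.39) and Il21r (5.67, next 7.73), and the highest Nr4a1 (5.70, next 4.41). Library 3 of that group had the lowest mean of lymphoid-primed genes (2.08, next 2.91), library 1 the highest type I interferon mean (6.94, next 6.38), library 4 the lowest Cxcl10 (-2.87, next 1.21) and library 7 the lowest Ano3 (-2.01, next 0.83). Irradiated vehicle library 8 at 24 h had the highest neutrophil marker mean (4.34, next 1.49) and the lowest cAMP target mean (2.5, next 3.06), and vehicle library 1 the lowest Cd83 (-2.87, next 0.20).

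At 1 h, irradiated dmPGE2 library 4 had the highest Gdf15 (6.63, next 5.09), Slc19a2 (6.62, next 5.24) and Pmaip1 (5.26, next 3.29). Library 6 of that group had the highest means of double-strand break repair (5.03, next 4.60) and G1/S genes (7.09, next 6.57) and the lowest of quiescence genes (5.18, next 5.47), library 3 the highest heat shock mean (7.19, next 6.39), library 7 the highest ribosomal protein mean (8.23, next 7.81) and library 8 the highest TMM factor (1.03, next 1.01). Irradiated vehicle library 3 had the highest Nr4a1 (7.54, next 5.23), Cd69 (10.18, next 9.20), Cd83 (7.43, next 5.90) and cAMP target mean (5.52, next 4.84), and the lowest Fam212b (4.90, next 5.89) and Sesn2 (8.57, next 9.05), and vehicle library 1 the highest Fos (6.31, next 4.32) and lowest Il10ra (0.33, next 2.22). Non-irradiated dmPGE2 library 2 had the highest immediate early mean (5.88, next 5.19) and Zfp36 (8.99, next 7.04), and library 5 the lowest share of counts in 10 genes (2.79%, next 3.04%).

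The dmPGE2 effect differed between 24 h and 1 h, tested as an interaction, in 3313 genes. Median differences of the lists that passed camera were 0.89 for p53 targets, -0.31 for double-strand break repair, -0.81 for G1/S, -0.91 for G2/M, 1.29 for NF-kB, -0.46 for oxidative phosphorylation, -0.21 for ribosomal proteins, 1.43 for neutrophil markers and -0.91 for megakaryocyte markers. Among genes, the log2 difference was 5.92 for Gdf15, 4.59 for Eda2r, 4.34 for Phlda3, 4.11 for Il10ra, 4.05 for Fam212b, -3.68 for Egr1, -3.38 for Nr4a1, -3.28 for Il21r and -2.97 for Thbd.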

How the results depend on the processing

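Fits without the libraries that lie apart and comparisons within 1 sex were chosen after seeing the data. So were fits with sex as a term, with the name tags as block and with 39 libraries for the sexes. All fits of radiation under dmPGE2 and of time were too, and the others were planned. Against a fold change of 1.5 with edgeR, 259 genes passed for dmPGE2 at 1 h, 200 at 24 h, 373 for the difference between times, 21 for radiation under dmPGE2 and 1824 for time. At an adjusted p below 0.01 the first 3 gave 1112, 1540 and 1758. For dmPGE2 at 24 h, 24 h libraries alone gave 1507, with a sex term 1800, and females within the fit of both sexes 42. The fit without libraries 5 to 7 gave 981 (882 shared with the 3037). Without library 3 too it gave 674 (624 shared), and 2158 for the difference between times. For sex, DESeq2 gave 462 and 39 libraries 675, and the fit without libraries 5 to 7 leaves 1 male dmPGE2 library. For dmPGE2 by sex, DESeq2 gave 34 and 39 libraries 90. Lists called were 7 for dmPGE2 at 1 h, 14 at 24 h, 9 for the difference, 13 for radiation under dmPGE2, 11 for time, 13 for sex and 7 for dmPGE2 by sex. Of these, an estimated correlation kept 1 for dmPGE2 at 1 h, 0 at 24 h, 4 for radiation under dmPGE2 and 0 for the difference between times, for time, for sex and for dmPGE2 by sex. The fry test called 9 lists for dmPGE2 at 1 h and 17 at 24 h (6 and 12 shared with camera), without the interferon list at either time (adjusted p = 0.22 and 0.27) or ribosomal proteins at 24 h (0.1). It called 15 for the difference between times, 5 for radiation, 20 for time, 8 for sex and 0 for dmPGE2 by sex.

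Leaving out 1 library at a time gave 1604 to 1936 genes for dmPGE2 at 1 h, 2347 to 3420 at 24 h, 2870 to 3591 for the difference, 49 to 61 for radiation, 6573 to 6897 for time, 14 to 1505 for sex and 0 to 864 for dmPGE2 by sex (1505 and 864 without dmPGE2 library 8). The cause of these moves was not tested. Without libraries 5 to 7, named genes lost their call in 6 of 20 cases for dmPGE2 at 24 h and in 1 of 10 for the difference between times. They lost it in 19 of 20 cases within females and in 4 of 20 within males (4 against 4 mice each, in 1 fit of both sexes). Direction changed in 0 cases. Named genes also lost their call in 8 of 30 cases without library 3 too, in 5 of 62 with the name tags as a replicate block (among them Dusp6 and Cd93 for radiation, adjusted p = 0.12 and 0.067), in 4 of 52 with libraries of that time alone and in 1 of 87 with DESeq2, which called 5 more. The scaling by RLE moved no call of the 87. Columns carry tags that recur across groups but not the labels' replicate numbers; same-tag libraries had correlations of 0.06 to 0.32 at 1 h (18 of 22 pairs over 0.1, 17 matching best within their tag), a hint from the data of a shared source, and 0.023 to 0.097 at 24 h (0 of 8 over 0.1, 5 matching best). All 8 tags at 1 h held libraries of a single sex by counts of Xist against the Y-linked genes, which also points to a shared source. The reported fit ignores any such pairing. The labels do not explain the tags, and as not every pair was over 0.1, the tags were tried only as an alternative. With them as a replicate block, 2228 genes and 8 lists passed for dmPGE2 at 1 h, 3647 and 18 at 24 h, 3854 and 10 for the difference, and 63 and 14 for radiation under dmPGE2. Lists called only with it were G2/M genes at 1 h (adjusted p = 0.0063), p53 targets (0.049), NF-kB genes (0.038), mast cell (0.04) and endothelial markers (0.043) at 24 h, lymphoid-primed genes for the difference (0.049), and homing (0.044) and ribosomal protein genes (0.026) for radiation, where pro-apoptotic genes were called only without it (0.022, and 0.057 with it). Depth limits the genes near the count minimum; thinning to the lowest total was run only for the gap of libraries 5 to 7. Not run: all alternatives of comparisons that need the unused columns, the labels' replicate numbers as block, and the fit without a sex term, which is the one reported.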

Other observations

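Single genes of prostaglandin signalling and cell survival differed with dmPGE2, although neither list was called for the difference between times. Of 17 PGE2 receptor and prostanoid genes 2 had a higher and 2 a lower response at 24 h (camera adjusted p = 0.67), and of 13 anti-apoptotic genes 2 and 2 (0.66). With edgeR, Ptger4, which encodes the PGE2 receptor EP4, was lower with dmPGE2 at 1 h and higher at 24 h, and the response differed between times by 1.58 (SE 0.21, adjusted p = 5.7e-07). At 24 h Ptges, a PGE2 synthase gene, rose by 0.73 (SE 0.22) and Ptgr1, which encodes an enzyme that inactivates prostaglandins, fell by 1.13 (SE 0.18). The survival genes Mcl1 and Xiap rose by 0.33 (SE 0.11) and 0.57 (SE 0.15) at 24 h, and so did the pro-apoptotic gene Bmf, by 2.37 (SE 0.69). Of these, Ptges, Mcl1, Xiap and Bmf were not called at 24 h without libraries 5 to 7 (0.52, 0.12, 0.48 and 1.10), and the response of Mcl1 was not called as different between times (0.28, SE 0.16, adjusted p = 0.21). Cxcr4, the receptor for the niche chemokine CXCL12, had a response 1.10 higher at 24 h (SE 0.31), and Selplg, a selectin ligand gene, rose at both times (0.97, SE 0.17 and 0.63, SE 0.17). Without the 3 libraries neither the difference of Cxcr4 (0.78, adjusted p = 0.064) nor the rise of Selplg at 24 h (0.24, adjusted p = 0.24) was called.

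Of the genes used to sort HSC, Fgd5 and Kit were not called with dmPGE2, while Slamf1 was called at 1 h. Fgd5 was at -0.07 (SE 0.14, adjusted p = 0.85) at 1 h and 0.23 (SE 0.14, adjusted p = 0.26) at 24 h, and Kit at -0.06 (SE 0.11) and 0.25 (SE 0.11). Slamf1 rose at 1 h by 0.68 (SE 0.16, edgeR adjusted p = 0.0028) and was not called at 24 h (0.36, SE 0.16, adjusted p = 0.11). From 1 h to 24 h with vehicle, Fgd5 fell by 0.58 (SE 0.14), while Ly6a, the gene of the sort marker Sca-1, rose by 1.26 (SE 0.15). Among regulators of quiescence, Btg1 and Foxo1 were lower at 24 h than at 1 h with vehicle (-1.88, SE 0.18 and -1.13, SE 0.23) and at 24 h higher with dmPGE2 than with vehicle (0.62, SE 0.18 and 0.80, SE 0.23). The cyclin gene Ccnd1 went the other way, with 2.81 (SE 0.32) over time and -0.83 (SE 0.30) with dmPGE2. With dmPGE2 at 24 h, Btg1, Foxo1 and Ccnd1 were not called without libraries 5 to 7 (0.22, 0.06 and -0.35).

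The tests of the next 3 patterns and the count of splits over autosomal genes were chosen after the results were seen, and the other counts of splits were planned, except that radiation under dmPGE2 and time are comparisons added after the columns were read. At 1 h p53 targets were lower with dmPGE2. A difference in library composition is argued against by TMM factors that differ by -0.016 (log2). Library size was scaled out before the test, and TMM factors do not measure it. Mislabelled libraries are argued against by 0 of 8 libraries within the range of another 1 h group. Of the 24 targets lower at 1 h, 2 were also lower at 24 h and 22 differed between times (median -1.83 at 1 h and -0.06 at 24 h). These 24 were picked by their 1 h values, which can enlarge their 1 h median and the count that differed. All 34 targets had medians of -1.07 and -0.06. The 95% half-width for a single one of the 24 genes at 24 h was 0.32, from their median SE. No interval was computed for the median of the genes. A candidate explanation, offered as a hypothesis and not tested, is that dmPGE2 delays the p53 response to radiation and that the delay is over by 24 h. Later induction and faster decay of these mRNAs were not separated. Nor was a fall with dmPGE2 that does not depend on radiation, since non-irradiated vehicle mice were not used.

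The 3 male dmPGE2 libraries that lie apart at 24 h are not explained by lower sequencing depth, since their gap to the other 13 was 0.80 of the range of those after thinning to 17371333 counts and 0.77 before. A shared batch of the name tags is argued against by 0 of 9 other libraries with these tags lying as far out, and a mixture with 1 h libraries by a G1/S mean 0.31 (log2) below the lowest of the 36 other libraries. Endothelial cells in the sort remain open. In the 3 libraries 4 of 10 markers (Pecam1, Cldn5, Emcn and Lyve1, at up to 6.54 log2 CPM) were above the 13 others, while Cdh5, Kdr and Plvap were not. Some of these genes are also expressed in HSC, and how well the sort removed endothelial cells was not tested. The sex of the mice cannot be told apart from chance, with 3 of 4 males and 0 of 4 females lying apart (Fisher exact p = 0.14, where 0.029 is the smallest that 4 against 4 can give).

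Cell cycle genes were lower with dmPGE2 at 24 h. The 3 male libraries are not the whole cause, since 20 of 55 G2/M genes were lower without them. A difference in library composition is argued against by TMM factors that differ by 0.027 (log2), which do not measure library size. Dilution by cells of another type would lower HSC identity genes, whose median was 0.25 (0.08 without the 3 libraries). Markers of other cells moved apart, with medians of -0.71 for megakaryocyte and 1.21 for neutrophil markers, so a change in the cells that carry the latter remains open. Fewer cycling cells and lower levels in each cell were not separated, and no biological explanation was tested.

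The same libraries were split into groups of the same sizes, with 100 splits per comparison, the real one included. In 5 comparisons no other split gave as many genes as the real one. With 100 splits this argues against chance at no finer than 1 in 100 and does not exclude it. The real counts and the highest of the other splits were 1929 and 647 for dmPGE2 at 1 h, 3037 and 1923 at 24 h, 3313 and 203 for the difference between times, 58 and 20 for radiation under dmPGE2, and 6944 and 5269 for time. The highest other split exchanged only dmPGE2 library 7 and vehicle library 1 at 1 h. At 24 h it exchanged only dmPGE2 library 3 and vehicle library 5, so both lay close to the real grouping. For sex (21 genes, and 1 in the highest other split) the outcome was fixed by the X- and Y-linked genes, 9 of which were called. Among 13551 autosomal genes, adjusted over these alone, 6 were called, and 0 in each other split. This count was chosen after the results were seen, and with 100 splits it does not exclude chance. Sex is not separated there from the 3 libraries that lie apart, all of male mice. For dmPGE2 by sex the count decides nothing: 100 of 100 splits gave at least the real 0, and the split with 21 genes exchanges the sexes among the vehicle mice, which turns the test into the comparison of the sexes.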
